A study of Mus musculus with 2 samples.

How the data were processed

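The series holds 2 single-cell libraries, 1 per group. Per the labels' protocols, mice received NaIO3 (20 mg/kg), the RPE and choroid were digested with collagenase and dispase, live CD45+ cells were sorted by flow cytometry, and libraries were made with a 3' kit of version v2. Per the submitters' processing notes, reads were aligned to mm10 and counted with Cell Ranger, whose version they do not state; per the file headers, the flox matrix was written by version 4 and the knockout matrix by version 7.0.1. The unit of the deposited matrices is the count of UMIs per gene and barcode, as whole numbers.

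The flox matrix holds 1002803 barcodes, 783281 of them with a UMI, more than the barcode list of a v2 kit holds, so the kit version given in the labels is uncertain for it. The knockout matrix holds 4096 called barcodes of at least 500 UMIs. To treat both alike, the same filter was applied: at least 1000 UMIs and 300 genes, less than 10% mitochondrial UMIs, and no doublet called by Scrublet. Of 3460 flox and 4024 knockout barcodes with 1000 UMIs, 3458 and 4024 passed the gene minimum, 3418 and 3982 the mitochondrial maximum, and 3396 and 3927 were kept after removal of 22 (0.644%) and 55 (1.38%) doublets at score thresholds of 0.304 and 0.274. The kept cells held 34716411 and 35030543 UMIs, with median mitochondrial shares of 1.504% and 1.58%. Of 32285 genes, 32235 matched the GENCODE vM21 annotation.

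Both libraries were clustered together on 2000 variable genes per library, 30 principal components, 15 neighbours and Leiden resolution 1.0 (seed 1), after scaling each cell to 10000 UMIs. Members of the functional gene lists (unless also cell type markers), mitochondrial, ribosomal, haemoglobin and Y-linked genes and Xist were left out of the variable genes. Clusters were named from 26 marker sets by a score against the 25th percentile of the clusters, at least 3 detected markers and the 10 leading genes. The thresholds of this naming rule were set after the clusters had been seen and several versions were tried, so the shares of the clusters it left unnamed are given beside those of the classes. Classes and clusters with at least 50 cells per library were compared. Sex was assigned per cell from Xist and Y-linked UMIs; that the libraries mix both sexes was seen only in the data.

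UMIs were summed per class and library and expressed as CPM, scaled to the class's total UMIs. Intervals at 95% are exact Poisson intervals for levels, conditional binomial intervals for ratios and Clopper-Pearson intervals for shares. With a count of 0, a limit of 3 counts is used. No test was made and no p-value given, as cells of 1 animal pool are not replicates. The 19 gene lists (type 17 programme, IL-17 receptor signalling, IL-17 response, inflammatory and repair macrophage, lipid and phagocytosis, type I interferon, MHC class II, interferon-gamma, complement, oxidative stress, proliferation, immediate early and stress, glycolysis and hypoxia, cytotoxic, regulatory T, T cell activation, neutrophil granule, growth and trophic factors) were summarised by the median log2 ratio over members with at least 20 UMIs in both libraries together, where at least 5 were measured, with 0.5 UMIs added. The percentile places this median among 10000 random lists matched by expression, as a description only. Outside the lists, genes were named by a fixed size rule. It asks for at least 100 UMIs in both libraries together, 50 CPM and detection in 10% of cells in the higher library, and a 95% interval of the ratio beyond 1.5-fold, ranked by ratio, up to 12 per direction in the 3 largest classes and 4 in the others. A few genes that met this rule or belong to the lists are not reported here on their own, and the gene ratio counts for other settings leave them out. Gene lists, marker sets, filters, settings and the first set of other settings below were chosen before the data were examined.

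Values were recomputed with UMI minima of 500 and 2000, mitochondrial maxima of 5% and 20%, doublets kept, Leiden resolutions of 0.5 and 2.0, another seed, each library clustered on its own, cells thinned to 1000 UMIs (for the shares of cells with a UMI, to 2000 or not at all), scaling by the median ratio, the mean of each cell's CPM, no UMI minimum for list members, 2 UMIs added, and subtraction of the RNA profile of flox barcodes with 100 UMIs or fewer. Chosen after the data had been seen were the split by sex, clustering without T cell receptor genes, medians per cluster, counting unnamed clusters into their nearest class, leaving out cluster 13, 17 or 21, leaving out the cluster that a gene leads, and leaving out the highest cell per gene. The minimum Jaccard overlap of 0.5 for matching clusters between settings was also added after first values had been seen.

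In a self-test, counts were simulated from the pooled profile of a class with 3-fold differences put into 200 genes. Of those that met the UMI and level minima, 100% were recovered in B cells, alpha-beta T cells and monocytes and 98.9% in gamma-delta T cells, and 0 unaltered genes were named. The intervals held the true ratio in 95.5% of genes in B, 95.6% in alpha-beta T, 95.7% in gamma-delta T cells and 95.7% in monocytes. Coverage near 95% follows from the design, as the simulated sums held counting error only. The simulation had no spread between cells or animals and left out the detection minimum. It therefore does not test the intervals of genes whose UMIs lie in few cells. Counts of near-identical genes, such as Hspa1a and Hspa1b, the Ifit and Ly6 families, and AC133103.1 on an unplaced scaffold, are uncertain as to which copy they come from. Tools were Python 3.11.15, scanpy 1.11.5 with its Scrublet, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.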

Results

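Single-cell RNA sequencing measured the messenger RNA of white blood cells (sorted on CD45, a surface protein of all white blood cells) from the tissue behind the retina. This tissue is the retinal pigment epithelium (RPE), the pigmented layer that nourishes the photoreceptors, and the choroid, the vascular layer beneath it. All mice received sodium iodate (NaIO3, 20 mg/kg, into the abdominal cavity), an oxidant that damages the RPE. The 2 libraries differ in genotype, with 1 library per group: one from mice carrying the floxed Il17ra gene (flox) and one from conditional Il17ra knockout mice (knockout). The series title names the question, whether cytokine signalling through interleukin-17 protects the RPE from degeneration. The comparison asks how the immune cells of this tissue differ when the IL-17 receptor is deleted. The cell type in which the gene was deleted, the exons removed and the number of animals pooled are not given in the sources used here. The flox library held 38623933 unique molecular identifiers (UMIs, each marking 1 captured RNA molecule) and the knockout library 35944330. After the same filter on both, 3396 flox cells had a median of 8707 UMIs and 2798 genes. The 3927 knockout cells had a median of 7668 UMIs and 2624 genes. No difference below has a replicate check, and every 95% interval, given in parentheses, covers counting error only. Levels are in CPM, a gene's UMIs scaled to the total UMIs of the cells named in that library.

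Il17ra itself, which encodes the receptor subunit shared by several IL-17 cytokines (ENSMUSG00000002897, protein-coding, chromosome 6, 120463247 to 120487559, plus strand, mm10), was detected at similar levels in both libraries. Over all kept cells it stood at 132 CPM (128 to 136) in flox and 123 CPM (119 to 127) in knockout, a ratio of 0.932 (0.894 to 0.972). The highest levels were in cluster 7, a monocyte-related cluster, at 383 CPM in flox and 384 CPM in knockout, and in monocytes at 237 and 229.8 CPM. The knockout over flox ratio was 0.766 (0.659 to 0.890) in B cells, 1.26 (1.14 to 1.39) in alpha-beta T cells and 1.23 (0.955 to 1.60) in natural killer (NK) cells. It was 0.855 (0.719 to 1.01) in type 2 dendritic cells and 0.862 (0.527 to 1.39) in gamma-delta T cells. The deleted part of the gene is not known here and a tag at the 3' end of the transcript that lies outside it checks nothing, so these values neither bear out nor contradict the genotype labels. With each cell thinned to 1000 UMIs the all-cell log2 ratio was 0.00 instead of -0.10, so no direction is drawn from it.

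B cells made up a larger share of the knockout library and monocytes and conventional dendritic cells a smaller one. B-like cells, the antibody-producing lineage, were 16.8% (15.6 to 18.1) of flox and 23.0% (21.7 to 24.4) of knockout cells, a difference of 6.18 percentage points (4.33 to 8.01). Monocyte-like cells, recruited phagocytes, were 13.7% (12.5 to 14.9) of flox and 9.57% (8.67 to 10.5) of knockout cells, a difference of -4.09 points (-5.59 to -2.60). Conventional dendritic cells of type 2, which present antigen to T helper cells, were 6.21% (5.42 to 7.08) and 3.59% (3.03 to 4.22), respectively. Those of type 1, which cross-present antigen to CD8 T cells, were 2.09% (1.64 to 2.63) and 0.993% (0.707 to 1.36). Alpha-beta T-like cells, at 32.9% (31.3 to 34.5) and 32.0% (30.5 to 33.4), and NK-like cells, at 6.83% (6.01 to 7.73) and 7.56% (6.76 to 8.43), differed by less than the counting error. Gamma-delta T-like cells, the main early source of IL-17A in many tissues, were 2.39% (1.90 to 2.96) and 1.58% (1.21 to 2.02), or 81 and 62 cells. These names rest on fixed markers, and the suffix is left out from here on.

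Rare classes were counted in few cells. Type 2 innate lymphoid cells numbered 7 in flox and 24 in knockout, microglia 22 and 12, tissue macrophages 2 and 10, and basophils 15 and 15. Mast cells numbered 6 and 2, neutrophils 13 and 12, plasmacytoid dendritic cells 16 and 16, mature dendritic cells 10 and 6, RPE-like cells 5 and 11, and photoreceptor-like cells 5 and 5. The naming rule kept 7 clusters out of every class, and their shares of the flox and knockout cells were as follows. Cluster 7, close to monocytes, was 9.31% (8.35 to 10.3) and 7.74% (6.92 to 8.62). Clusters 18 and 22, close to alpha-beta T cells, were 3.21% and 1.78%, and 0.412% and 5.50%. Cluster 6, between gamma-delta and alpha-beta T cells, was 1.18% and 1.38%, and cluster 20, close to B cells, 1.27% and 1.502%. Cluster 27, of cycling cells, was 0.589% and 0.662%, and cluster 29, close to microglia, 0.147% and 0.280%. All these shares are shares of CD45-sorted cells, which the sort and the tissue digestion help to set. With each library clustered on its own, the monocyte difference was 3.63 points and the gamma-delta T difference 0.543, because cells of clusters 7 and 6 then joined these classes in the knockout library.

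**Figure D1:**
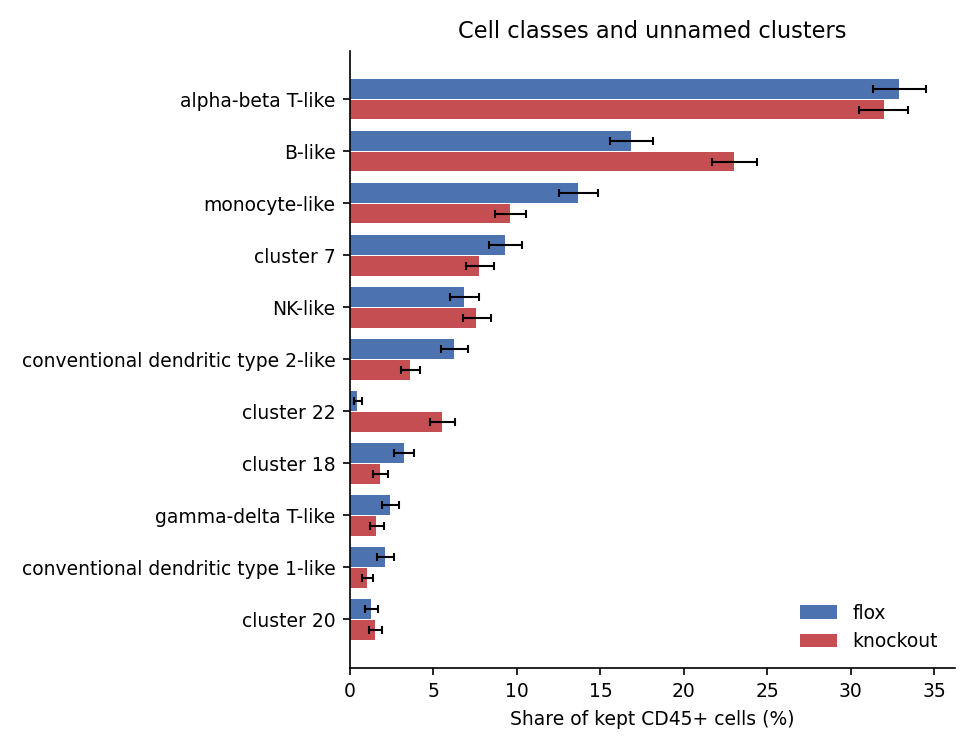
Share of each library's kept cells (percent, horizontal axis) in the larger named classes and numbered clusters. There is 1 bar per library, with exact 95% binomial intervals. Classes and clusters smaller than cluster 20 (43 flox and 59 knockout cells) are not drawn. B cells were 16.8% of flox and 23.0% of knockout cells, and monocytes 13.7% and 9.57%.

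The cells came from animals of both sexes in unequal mixes, which the labels do not mention. By Xist, the RNA that silences an X chromosome in females, and by Y-linked transcripts, 65.7% (64.1 to 67.3) of flox cells were female and 15.8% (14.6 to 17.1) male, against 39.3% (37.7 to 40.8) and 34.7% (33.2 to 36.2) of knockout cells. The others had UMIs of neither or of both. The share difference of B cells was 13.8 points in female and -3.54 points in male cells, and that of alpha-beta T cells -10.1 and 9.03 points. It was 3.46 and -1.35 points for NK cells, -0.0889 and 2.57 for cluster 7, and -0.797 and -0.426 for gamma-delta T cells. Monocytes were lower in the knockout library in both sexes, by -3.47 points in female and -5.68 points in male cells. Type 2 dendritic cells differed by -4.27 and -2.01 points. Their male difference, from 32 flox and 54 knockout cells, lay within counting error. The alpha-beta T cell difference therefore does not hold within both sexes, and that of B cells was seen in female cells only.

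A pair of T cell clusters consisted mostly of knockout cells. Cluster 21, part of the alpha-beta T class and expressing the CD8 genes, held 26 flox cells (0.766%, 0.501 to 1.12) and 281 knockout cells (7.16%, 6.37 to 8.01). Cluster 22 held 14 flox cells (0.412%, 0.226 to 0.691) and 216 knockout cells (5.50%, 4.81 to 6.26). Cd4, the co-receptor of helper T cells, had a UMI in 0 of 216 knockout cells, which allows a share of up to 1.39%. Both clusters together were 5.27 points higher in the knockout library among female cells and 14.3 points higher among male cells. Of the other alpha-beta T clusters, cluster 10 held 480 flox and 357 knockout cells, cluster 2 held 316 and 254, and cluster 14 held 134 and 107. Cluster 16, of naive-like cells, held 124 and 256, and cluster 15 held 37 and 0, which allows up to 0.0764% of knockout cells. With 1 library per group, a cluster made mostly of 1 library can be a trait of that library and not a cell type.

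**Figure D2:**
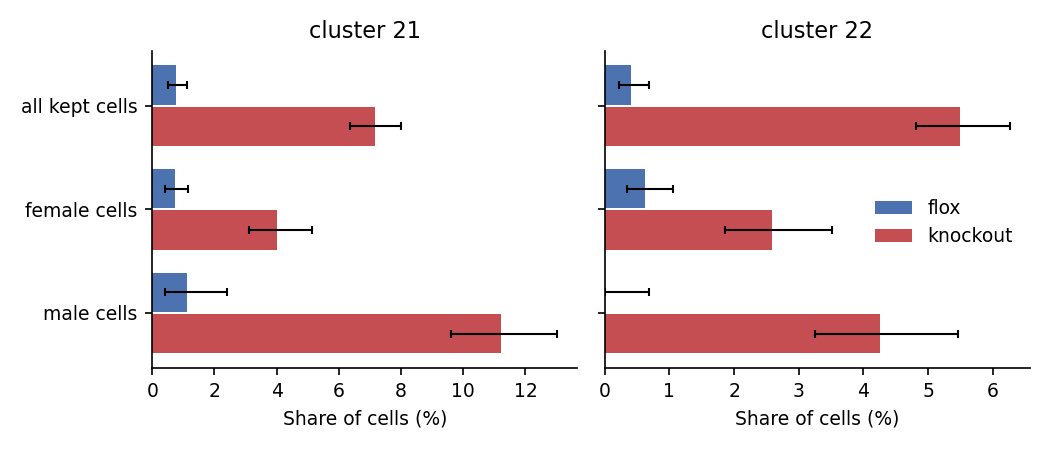
Shares of cluster 21 (left) and cluster 22 (right) in percent of all kept, female and male cells (horizontal axis), with 1 bar per library and exact 95% binomial intervals. Cluster 21 was 0.717% of flox and 4.02% of knockout female cells, and 1.12% and 11.2% of male cells.

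Genes induced by type I interferon, the antiviral programme, were lower in the knockout library in every class measured. Over all kept cells 15 of 15 measured members were lower, with a median log2 ratio of -1.34 (-1.39 to -1.23), below all 10000 random lists of genes of like expression (percentile 0). Rsad2, an antiviral enzyme, stood at 82.4 CPM in flox and 15.6 CPM in knockout, Ifit1, which binds viral RNA, at 90.1 and 21.1, and Ifit3 at 129 and 35.3. The median was -1.54 (-1.61 to -1.41) in alpha-beta T cells with 15 of 15 lower and -0.99 (-1.12 to -0.85) in monocytes with 15 of 15 lower. It was -0.84 (-1.04 to -0.75) in type 2 dendritic cells with 15 of 15 lower, and -0.69 (-1.02 to -0.61) in cluster 7 with 15 of 15 lower. In cluster 18 it was -1.89 (-2.09 to -1.54) with 14 of 14 lower, in NK cells -0.53 (-0.75 to -0.31) with 11 of 12 lower, and in B cells -0.36 (-0.58 to -0.23) with 12 of 12 lower. Gamma-delta T cells had -1.94 (-2.66 to -1.42) with 10 of 10 lower, but their female cells, 67 of the 81 flox cells, had -0.31 (-0.90 to 0.18) over 6 members. The percentile was 0 in each class except B cells, where it was 0.08. By sex, the all-cell median was -1.11 in female and -1.98 in male cells, the B cell median 0.04 and -1.28, and the cluster 7 median -0.75 and 0.29, the last from 20 male flox cells. It was -1.38 and -2.59 in alpha-beta T cells, -0.79 and -1.54 in monocytes, -0.94 and -1.71 in type 2 dendritic cells and -0.31 and -1.05 in NK cells. Female cells alone gave -1.89 in cluster 18. Within single clusters the median was below 0 in 14 of 14 clusters with at least 50 cells per library, and below -0.5 in 9 of them. The interval lay below 0 in 11. The median was -0.05 (-0.23 to 0.09) in cluster 17, a monocyte cluster, and -0.30 (-0.42 to 0.03) in cluster 16. It was -0.45 (-0.61 to 0.00) in cluster 11, of NK cells.

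**Figure D3:**
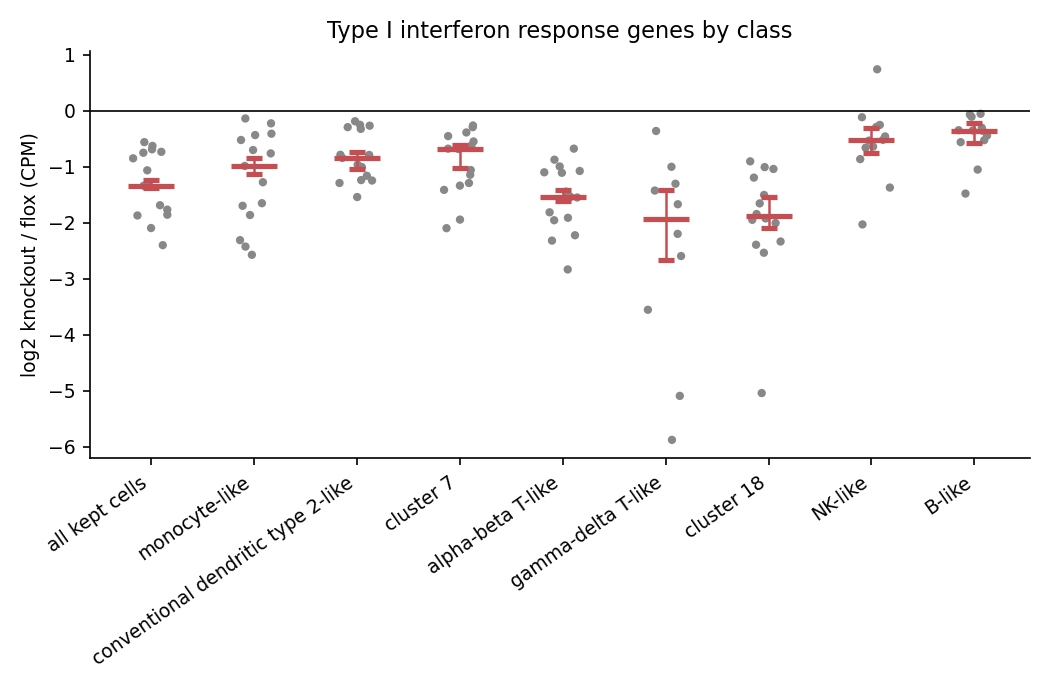
Log2 ratio of CPM (knockout over flox, vertical axis) of each measured type I interferon gene (grey points), with the median and its 95% interval for counting error (red), in all kept cells and in each class or cluster with at least 50 cells per library. The medians run from -0.36 in B cells to -1.94 in gamma-delta T cells, and 1 gene in NK cells lies above 0.

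Monocytes of the knockout library had lower levels of interferon-induced genes, of complement genes and of Cxcl10, a chemokine that attracts activated T cells. Most monocytes of both libraries lay in cluster 9 (411 flox and 299 knockout cells), the rest in cluster 17 (53 and 77). Cxcl10 stood at 408 CPM (393 to 423) in flox and 36.7 CPM (31.9 to 42.1) in knockout, 11.1-fold lower (9.64 to 12.8), with its flox UMIs in 88 of 464 cells. Ifit1 was 5.97-fold lower (5.02 to 7.14), Rsad2 5.39-fold (4.71 to 6.19), and Ifit2 4.98-fold (4.28 to 5.81). Ifit3 was 3.64-fold lower (3.25 to 4.09), Isg15, a ubiquitin-like modifier, 3.25-fold (3.04 to 3.47), and Usp18, which removes it, 3.15-fold (2.64 to 3.78). The other named genes that were lower were Ly6a, a surface antigen, 5.60-fold (4.67 to 6.76) with 19.7% of its flox UMIs in 1 cell, and Spon1, a matrix protein, 3.66-fold (2.91 to 4.63). They also included Slfn4 2.91-fold, Phf11d 2.78-fold, and Il1rn, the natural antagonist of interleukin-1, 2.57-fold (2.11 to 3.15). The genes named as higher were Slc15a2, a peptide transporter, 1.86-fold (1.59 to 2.17), and Cd300lb, an activating receptor, 1.71-fold (1.51 to 1.93). Of the interferon-gamma list, 10 of 11 members were lower (median -0.97, -1.15 to -0.80, percentile 0), among them the immunity-related GTPase Iigp1 (14.05 CPM in flox and 1.24 CPM in knockout) and Gbp4 (8.87 and 1.42). Of the complement list, 9 of 10 were lower (median -0.78, -1.08 to -0.52, percentile 0). C1qa, a part of the first complement component, stood at 43.9 and 9.05 CPM in few cells (23 flox cells), and Cfb, of the alternative pathway, at 43.3 and 13.7 CPM. The oxidative stress list had 12 of 13 lower (median -0.29, -0.33 to -0.19), with Hmox1, which breaks down haem, at 179 and 103 CPM (a leading gene of cluster 17, with 127 and 110.4 CPM without it). The neutrophil attractant Cxcl2 stood at 527 and 275 CPM. The immediate early and stress list had 12 of 14 higher (median 0.13, 0.10 to 0.17).

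In alpha-beta T cells, interferon-induced and regulatory T cell genes were lower in the knockout library and genes of cytotoxic effector cells higher. The latter lay in part in cluster 21, which held 82.7% of the class's knockout UMIs of Klrg1, 41.0% of Ifng and 17.8% of Tnf. Ikzf2, the transcription factor Helios of regulatory and innate-like T cells, stood at 288 CPM (278 to 299) in flox and 102 CPM (96.1 to 109) in knockout, 2.82-fold lower (2.63 to 3.03). It leads cluster 2, of CD4 cells, and without that cluster its knockout over flox ratio was 0.328 (0.294 to 0.364). Without cluster 21 the ratio of Ikzf2 was 0.417 (0.388 to 0.448), so the mix of clusters accounts for part of its difference. All 8 members of the regulatory T list were lower (median -0.75, -0.98 to -0.68, percentile 0). Among them were Foxp3, the factor that specifies regulatory T cells (14.9 and 8.78 CPM), the anti-inflammatory cytokine Il10 (13.7 and 3.90, with 27.6% of the flox UMIs in 1 cell) and the co-stimulatory receptor Tnfrsf4 (64.5 and 26.0; also leading cluster 2, ratio 0.281 without it). The other genes named as lower were Rsad2 (5.01-fold, 4.12 to 6.14), Ifit1 (3.89-fold), Ifit3 (3.77-fold), Usp18 (3.53-fold), Slfn5 (3.23-fold) and A330040F15Rik (3.11-fold). To these come Isg15 (2.91-fold), Ifi27l2a (2.72-fold), the endosome protein Eea1 (2.71-fold), the tetraspanin Cd9 (2.52-fold) and the adhesion molecule Alcam (2.51-fold). The interferon-gamma list had 10 of 10 lower (median -0.64, -0.75 to -0.48). The T cell activation list had 8 of 9 lower (median -0.58, -0.65 to -0.50), with the inhibitory receptor Lag3 at 39.4 and 12.6 CPM. This class leaves out cluster 22, of 14 flox and 216 knockout cells, whose leading genes include Pdcd1, of the activation list. No list was recomputed with that cluster. Over all kept cells the activation list had 5 of 9 lower and a median of -0.11. The immediate early and stress list had 10 of 14 higher in the class (median 0.23, 0.09 to 0.29). The genes named as higher were Klrg1, a receptor of terminal effector cells (3.95-fold, 3.26 to 4.82), Trat1, a T cell receptor adaptor (2.60-fold), and the transcription factor Zeb2 (2.51-fold). Also higher were the interleukin-12 receptor subunit Il12rb2 (2.42-fold), the collagen-binding integrin Itga1 (2.39-fold), Igfbp4 (2.18-fold), and Nebl (2.16-fold). The last of them were the chemokine Ccl4 (1.98-fold), Tnf (1.91-fold), Fgl2 (1.83-fold), Ifng, encoding interferon-gamma (1.76-fold, 1.64 to 1.89), and the activating receptor Klrk1 (1.68-fold). Klrg1, Nebl and Ifng are among the leading genes of cluster 21, Igfbp4 of cluster 16 and Trat1 of cluster 2. Without cluster 16 the ratio of Igfbp4 was 0.662 (0.198 to 2.01), and without cluster 2 that of Trat1 was 2.62 (2.13 to 3.23). Without cluster 21 the knockout over flox ratio was 1.06 for Klrg1, 0.971 for Zeb2, 1.11 for Nebl, 1.07 for Klrk1, and 0.757 for Ccl4. It was 1.25 for Il12rb2, 1.07 for Fgl2, 1.28 for Ifng, 1.66 for Itga1, 1.88 for Tnf and 2.31 for Trat1. The cytotoxic list had 5 of 8 members higher (median 0.20, 0.15 to 0.25), with the granule protease Gzma at 131 and 738 CPM, and a median of -0.36 without cluster 21. Most flox cells of the class lay in clusters 10 and 2, and most knockout cells in clusters 10, 21 and 16.

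In B cells no gene met the naming rule as higher, and the genes named as lower shared a small cluster of flox cells. Ccnd2, a cyclin that drives entry into the cell cycle, stood at 134 CPM (123 to 146) in flox and 18.8 CPM (15.5 to 22.7) in knockout, 7.11-fold lower (5.77 to 8.82). Lgals1, a galectin, was 5.86-fold lower (4.87 to 7.09), Ddt, a relative of the cytokine Mif, 4.80-fold (4.16 to 5.56), and the scaffold protein Ahnak 3.74-fold (3.35 to 4.18). The others were AC133103.1 (8.85-fold), the integrin Itgb1 (3.62-fold), C130026I21Rik (3.44-fold), Ass1 (3.37-fold), the adhesion receptor Cd44 (2.95-fold), Pycard (2.94-fold), Syne1 (2.89-fold) and Gng12 (2.88-fold). Cluster 13, with 54 flox and 27 knockout cells, held between 64.2% (Syne1) and 92.2% (Lgals1) of their flox UMIs, and AC133103.1 and C130026I21Rik are among its leading genes. Without it the ratios ranged from 0.564 for Ccnd2 to 1.30 for Pycard. Most B cells of both libraries lay in clusters 4 (319 and 564) and 5 (199 and 313). The lipid and phagocytosis list had 8 of 8 measured members lower in B cells (median -0.48, -0.92 to -0.28), and the MHC class II list, of antigen presentation, 8 of 9 with a median of -0.06 (-0.09 to -0.02).

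Cluster 7 had lower MHC class II and interferon-gamma genes in the knockout library, and higher Apoe, Id3 and Pltp. All 9 members of the MHC class II list were lower (median -1.42, -1.66 to -1.37, percentile 0). H2-Eb1 stood at 557 CPM in flox and 87.9 CPM in knockout, H2-Aa at 725 and 169, and Ciita, the master regulator of these genes, at 14.1 and 2.22. The interferon-gamma list had 10 of 10 lower (median -1.01, -1.62 to -0.86). The immunity-related GTPase Iigp1, with 416 flox UMIs in 24.7% of cells and 0 knockout UMIs, was at least 123-fold lower against a floor of 3 counts in the library. Gm4951, with 319 UMIs and 0, was at least 94.5-fold lower. The protease inhibitor Serpina3g had 194 and 3 UMIs, a ratio of 0.0174 (0.00356 to 0.0516), and the uridine phosphorylase Upp1 was 29.6-fold lower (13.4 to 81.7). Apoe, the lipid carrier, stood at 1745 and 3384 CPM, a ratio of 1.94 (1.87 to 2.01), while the lipid and phagocytosis list had 5 of 10 higher (median 0.00, -0.13 to 0.13, percentile 34.2). The named genes that were higher were Id3, an inhibitor of transcription factors (2.33-fold, 1.82 to 2.997), the phospholipid transfer protein Pltp (2.22-fold, 1.84 to 2.69), Slc15a2 (2.21-fold, 1.66 to 2.95) and transferrin, Trf (2.05-fold, 1.72 to 2.44). The complement list had 4 of 6 lower (median -0.57, -0.88 to -0.31), and the immediate early and stress list 13 of 14 higher (median 0.14, 0.11 to 0.26). Il10 stood at 33.5 and 7.39 CPM, with 24.5% of its flox UMIs in 1 cell.

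Type 2 dendritic cells, all in cluster 1, had higher heat shock genes and lower interferon genes in the knockout library. Hspa1a, a heat shock chaperone, was 2.67-fold higher (2.30 to 3.11) and its near-identical paralog Hspa1b 2.12-fold (1.79 to 2.504). Of the immediate early and stress list, 14 of 14 members were higher (median 0.35, 0.28 to 0.38). Arhgap6, a regulator of the cytoskeleton, was 2.18-fold higher (1.64 to 2.90). Fabp5, a fatty acid carrier, was 3.52-fold lower (2.52 to 5.04), Ifit1 2.93-fold (2.25 to 3.86), Ly6a 2.86-fold (2.38 to 3.45), and the chemokine Ccl5 3.13-fold (2.73 to 3.62) with 35.5% of its flox UMIs in 1 cell. The complement list had 6 of 7 higher (median 1.29, 0.98 to 1.61), with C1qa at 21.1 and 79.8 CPM and C1qc at 15.9 and 62.4 CPM. All knockout UMIs of C1qa lay in 10 of 141 cells. Cxcl9, of the interferon-gamma list, stood at 9.04 and 62.4 CPM, with 97.1% of its knockout UMIs in 1 cell. Proliferation genes had 9 of 9 lower (median -0.67, -1.05 to -0.36), and a median of 0.60 with each library clustered on its own.

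NK cells had higher Klf2 and lower Spp1 in the knockout library. They lay in cluster 11 (174 flox and 243 knockout cells) and cluster 0 (58 and 54). The genes named in NK cells were not compared within each cluster, so a different mix of both clusters may contribute. Klf2, a factor of quiescence and of exit from tissue, stood at 604 CPM in flox and 1056 CPM in knockout, 1.75-fold higher (1.63 to 1.88). Spp1, osteopontin, was 5.20-fold lower (3.36 to 8.37), the immediate early gene Fosb 2.21-fold (1.63 to 3.02), Pmepa1 2.15-fold (1.55 to 3.002) and the co-stimulatory receptor Tnfrsf9 1.77-fold (1.54 to 2.02). The immediate early and stress list as a whole had 8 of 13 higher (median 0.31, 0.06 to 0.39), but a median of -0.0668 with cells thinned to 1000 UMIs. The interferon-gamma list had 8 of 9 lower (median -0.41, -0.58 to -0.17), while the chemokine Ccl3 stood at 329 and 474 CPM and the granule protease Gzmb at 1552 and 1253 CPM. In cluster 18, of T cells, Frmd4b (2.44-fold, 1.61 to 3.74), Kcnq1ot1 (2.16-fold, 1.55 to 3.04) and the stress gene Gadd45b (2.001-fold, 1.57 to 2.56) were higher. Lower were Isg15 (5.86-fold, 4.28 to 8.23), Ifit3 (5.35-fold), Irf7, a factor that amplifies the interferon response (4.08-fold), and Ifit1 (3.93-fold). Thinned to 1000 UMIs per cell, the log2 ratio of Frmd4b was -0.25.

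Il17a was detected mostly in gamma-delta T cells, at a higher level there in the knockout library and a similar one over all cells. It is a leading gene of their cluster, but was neither a marker for naming nor among the variable genes. Il17a, encoding the cytokine IL-17A (chromosome 1, 20730905 to 20734496, mm10), had 608 flox and 650 knockout UMIs over all cells, 17.5 and 18.6 CPM, a ratio of 1.06 (0.947 to 1.19). Gamma-delta T cells held 87.2% and 84.6% of them. In gamma-delta T cells Il17a stood at 847 CPM in flox and 1212 CPM in knockout, a ratio of 1.43 (1.27 to 1.61), and Il17f at 15 and 24 UMIs, a ratio of 2.21 (1.11 to 4.52). The interleukin-23 receptor Il23r stood at 724 and 729.5 CPM, a ratio of 1.01 (0.872 to 1.16). Thinned to 1000 UMIs per cell, 35.8% (25.4 to 47.2) of flox and 41.9% (29.5 to 55.2) of knockout gamma-delta T cells had an Il17a UMI, a difference of 6.13 points (-10.7 to 22.9). With doublets kept the difference was -11.1 points, so its direction is not settled. Of B cells, thinned alike, the same held for 0 of 572 and 0 of 904, which allows shares of up to 0.524% and 0.332%. Unthinned, the gamma-delta T shares were 60.5% and 64.5%, at median depths of 7420 and 6527 UMIs in gamma-delta T cells and 5986.5 and 6294.5 in B cells. Il22, a cytokine acting on epithelia, had 12 UMIs in each library, 6 of them in gamma-delta T cells of the flox library and 11 in cluster 6 of the knockout library. It was detected in only 0.0589% of flox and 0.0764% of knockout cells, and in 1.23% of the 81 flox gamma-delta T cells. No change of source is drawn from so few cells. In alpha-beta T cells Il17a had 29 and 15 UMIs, a ratio of 0.493 (0.246 to 0.949), but in only 4 and 2 cells, a share difference of -0.199 points (-0.772 to 0.291). Il17f had 9 and 2 UMIs there, in 5 and 2 cells. The type 17 list was lower in alpha-beta T cells (8 of 12 members, median -0.47, -0.68 to -0.19) and mixed in gamma-delta T cells (6 of 14 higher, median -0.04, -0.14 to 0.10). With each library clustered on its own, the gamma-delta T class of the knockout library included cluster 6 and the log2 ratio of Il17a was -0.31.

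Several interferon-induced genes were lower in gamma-delta T cells of the knockout library, and some of the genes named here rested on few cells. For female cells alone, 67 of the 81 flox cells, the interferon list median given above was -0.31 (-0.90 to 0.18). Ifit3, with 40 flox UMIs and 0 knockout UMIs, was at least 9.67-fold lower against the floor of 3 counts in the library, Cxcl10 (27 and 0) at least 6.53-fold and Rsad2 (23 and 0) at least 5.56-fold. Isg15 was 6.25-fold lower (3.51 to 12.1) with 35.7% of its flox UMIs in 1 cell, Gm11290 4.22-fold (2.51 to 7.54) with 36.4% in 1 cell, Ly6a 3.30-fold (2.16 to 5.22) and Ms4a6b 3.05-fold (1.94 to 4.98). Ccl5 was 2.28-fold higher (1.93 to 2.69), but 1 of 62 knockout cells held 61.8% of its UMIs and 80.5% of those of Gzma. The cytotoxic list had 4 of 6 higher and a median of 0.93 (0.39 to 1.19), and without that cell, a check chosen after seeing the data, 1 of 6 higher and a median of -0.23. The others named as higher were the potassium channel Kcnq5 (2.23-fold, 1.65 to 3.05, 23.5% of UMIs in 1 cell), the acetyltransferase Kat6b (2.22-fold, 1.56 to 3.18) and Osbpl8 (2.09-fold, 1.53 to 2.86).

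Over all kept cells, the lists furthest below 0 beside the interferon list were those of interferon-gamma response, regulatory T cells and IL-17 response genes, and the cytotoxic list was the furthest above. The interferon-gamma list had 10 of 11 members lower (median -0.64, -0.72 to -0.52, percentile 0), with Cxcl10 at 118 and 13.6 CPM. The regulatory T list had 8 of 8 lower (median -0.59, -0.80 to -0.39, percentile 0), with Ikzf2 at 109.5 and 49.8 CPM. The IL-17 response list, of chemokines and antimicrobial proteins that IL-17 induces in many cell types, had 9 of 12 lower (median -0.41, -0.60 to -0.34, percentile 0), with S100a8 at 169 and 73.7 CPM. S100a9 stood at 192 and 90.4 CPM and the iron-binding Lcn2 at 3.46 and 1.48 CPM; these genes are also made by neutrophils, of which there were 13 and 12. In the 2 classes with enough members measured, the median lay within counting error of 0, with 4 of 8 higher in monocytes (-0.01, -0.20 to 0.18, percentile 38.7) and 3 of 6 in type 2 dendritic cells (-0.15, -0.46 to 0.11, percentile 10.5). In the latter, Cxcl1 had 25 and 0 UMIs, at least 5.12-fold lower against the floor of 3 counts in the library. The neutrophil granule list, which shares Lcn2 and Mmp9 with it, had 5 of 5 lower (median -0.31, -0.48 to -0.27, percentile 2.43). The cytotoxic list had 7 of 8 higher (median 0.26, 0.25 to 0.28, percentile 99.99), with Ifng at 47.6 and 99.4 CPM and Gzma at 729 and 1040.5 CPM. MHC class II had 7 of 9 lower (median -0.29, -0.31 to -0.27, percentile 0.01), complement 6 of 10 (median -0.26, -0.37 to -0.08, percentile 0.04) and growth and trophic factors 7 of 11 (median -0.20, -0.24 to 0.00, percentile 0.97).

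The remaining lists had medians nearer 0 over all kept cells. Inflammatory macrophage genes had 10 of 16 lower (median -0.18, -0.21 to -0.15, percentile 0.08), glycolysis and hypoxia 11 of 12 (median -0.17, -0.21 to -0.14, percentile 0.17) and the oxidative stress response 10 of 14 (median -0.17, -0.20 to -0.15, percentile 0.24). Within the last, the cystine transporter Slc7a11 stood at 43.6 and 24.2 CPM and Hmox1 at 41.9 and 24.0 CPM, while Nqo1, a quinone reductase, stood at 0.403 and 0.799 CPM. T cell activation had 5 of 9 lower (median -0.11, -0.14 to -0.07, percentile 3.69), lipid and phagocytosis 9 of 15 (median -0.10, -0.20 to -0.01, percentile 1.97), proliferation 12 of 14 (median -0.05, -0.11 to 0.01, percentile 6.37) and the type 17 programme 9 of 16 (median -0.02, -0.16 to 0.05, percentile 21.4). IL-17 receptor signalling had 9 of 15 higher (median 0.06, -0.05 to 0.12, percentile 80.2), repair macrophage genes 7 of 14 (median 0.06, -0.11 to 0.16, percentile 59.2) and immediate early and stress genes 8 of 14 (median 0.08, 0.04 to 0.11, percentile 96.5), with Hspa1a at 23.0 and 36.2 CPM. All-cell values mix differences within classes with the different shares of those classes.

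Markers of cells outside the CD45 sort were detected in both libraries. Of the sets below, only RPE and photoreceptor markers named a cluster. The sums of the other sets do not show which cells made the RNA, and white blood cells are not excluded as their source. Endothelial and Schwann cell markers stood at 97.4 and 178 CPM in flox free RNA, no higher than in flox cells (138 and 190 CPM). Summed RPE markers, such as the retinoid enzyme Rpe65 and the thyroid hormone carrier Ttr, stood at 67.9 CPM in flox and 277 CPM in knockout, a ratio of 4.07 (3.89 to 4.26). Of the Ttr UMIs, 98.0% and 96.5% lay in the RPE-like cluster of 5 and 11 cells. Fibroblast markers stood at 1.76 and 10.2 CPM, a ratio of 5.80 (4.41 to 7.74), and photoreceptor markers at 46.5 and 23.1 CPM, a ratio of 0.496 (0.456 to 0.541). Erythroid markers had a ratio of 0.485 (0.387 to 0.606), platelet markers 1.46 (1.201 to 1.79), mural cell markers 1.38 (1.06 to 1.82), melanocyte markers 1.18 (1.07 to 1.30), Schwann cell markers 1.09 (1.06 to 1.13) and endothelial markers 0.872 (0.836 to 0.909).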

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

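Of the tests below, those of intron counting, of sex for the T cell clusters and of a library effect were chosen only after the result was seen, and that of free RNA from RPE cells was altered after its result was seen.

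Type I interferon genes were lower in the knockout library in every class, and genotype is 1 of several explanations. Counting of intronic reads by the later software version is excluded as the cause, as genes with over 100 kb of intron and intronless genes differed by only -0.10 in median log2 ratio. Animals of 1 sex alone are excluded for the all-cell median, which was -1.11 in the sex nearer 0. They are not excluded for B cells, where the female median was 0.04. Within each library the list was also higher in male than in female cells, with 15 of 15 members higher. The male over female median was 1.36 (1.24 to 1.49) in flox and 0.59 (0.48 to 0.68) in knockout. The list thus varied between pooled animals of 1 genotype, though all-cell values also mix class shares. Free RNA from interferon-induced cells would need to make up 3.97% of the UMIs of flox B cells, and Lyz2, a monocyte gene, allows 0.684% (at most 0.818%), so it is excluded for B cells. Another mix of cell states stays open, with 9 of 14 clusters below -0.5, and so does genotype, with 1 library per group. An infection or a different time of death of the flox animals could give the same pattern, and further animals per genotype with Rsad2 and Cxcl10 measured by quantitative PCR would separate these from an effect of the receptor.

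Clusters 21 and 22 were nearly absent from the flox library. T cell receptor segments do not cause them, as without these genes the smaller difference was still 4.86 points. The sex mix alone does not cause the summed difference of both clusters, which was 5.27 points in the sex with the smaller difference. Cluster 21 differed by 3.30 points in female and 10.1 in male cells, and cluster 22 by 1.97 and 4.25. Of the 216 knockout cells of cluster 22, 40 were female and 58 male, and the others had no assigned sex. The test left these others out, so it does not settle cluster 22 on its own. A library effect that separates all T cells is excluded, as cluster 10, of CD8 cells too, was made up of knockout cells to 42.7%. This does not exclude a library effect on some T cells only. Such a library effect, an expansion of effector T cells in 1 or few of the pooled animals and an effect of the deletion cannot be told apart with 1 library per group. Receptor sequencing of single animals might resolve part of this.

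RPE transcripts were higher in the knockout library. More RPE cells passing the sort stay open: 96.5% of the knockout Ttr UMIs lay in the RPE-like cluster, but Ttr helps to define it, and its share differed within counting error, with 5 and 11 cells and a ratio of 1.90 (0.609 to 6.98). Only 3.53% lay outside the cluster, so free RNA spread over all cells does not account for most of these UMIs. By the test first written, free RNA is not excluded. The test first written asked for a Ttr ratio outside the cluster of at least 2, and this was met at 9.10 (6.01 to 14.4); it was set aside because 183 of the 229 knockout UMIs there lay in 1 dendritic cell, and without the highest cell of each library the ratio was 1.99 (1.18 to 3.43), so some more free RNA remains possible. Differing survival of the RPE after NaIO3 could also lie behind it, but 5 and 11 cells left over from a CD45 sort do not measure RPE loss.

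Several differences had opposite signs in the 2 sexes, most of them within counting error in 1 sex, and differences between the sexes were not tested. The share of alpha-beta T cells differed by -10.1 points (-13.0 to -7.16) in female and 9.03 (4.12 to 13.8) in male cells. That of B cells differed by 13.8 (11.04 to 16.5) and -3.54 (-7.80 to 0.523), that of NK cells by 3.46 (1.66 to 5.32) and -1.35 (-3.93 to 0.883), and that of cluster 7 by -0.0889 (-2.04 to 1.92) and 2.57 (0.248 to 4.597). The interferon median was 0.0411 (-0.22 to 0.21) and -1.28 (-1.60 to -0.89) in B cells, and -0.75 (-0.99 to -0.56) and 0.29 (0.16 to 0.74) in cluster 7. As the libraries hold different sex mixes, the pooled shares of these classes may reflect the animals pooled, as may the interferon sizes, given -1.11 in the sex nearer 0. Barcodes with 100 UMIs or fewer in the flox library held 4691 haemoglobin UMIs (1459.8 CPM, 1418 to 1502), from lysed red cells likely, and free RNA was not subtracted from the values reported; its share was estimated from haemoglobin at 0.464% of flox and 0.199% of knockout UMIs, the latter with the free RNA profile of the flox library.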

How the results depend on the processing

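No paired analysis was possible because each group holds replicate 1 only and nothing pairs the animals. Over the planned settings, 77 of 85 share differences, 60 of 69 interferon medians, 766 of 888 other list medians, 569 of 701 gene ratios and 18 of 24 UMI shares stayed within the 95% interval of the value reported, and 3, 0, 12, 4 and 0 reversed. Reversed means that a value whose interval left out 0 took the other sign. Counting every value, the sign was kept in 79, 69, 801, 680 and 15 of them. These counts hide differences between settings: with cells thinned to 1000 UMIs only 40 of 102 gene ratios and 39 of 75 other list medians stayed within the interval, and with the mean of each cell's CPM 67 of 102 gene ratios. Many fold sizes thus moved under these settings. Thinning also discards counts, and the sampling noise this adds was not separated from an effect of depth. Unless stated, the cause was not tested. In female cells only, chosen after seeing the data, the share differences were 13.8 points for B, 3.46 for NK, -10.1 for alpha-beta T cells, -0.0889 for cluster 7, -4.27 for type 2 dendritic cells, 3.30 for cluster 21 and 1.97 for cluster 22. The interferon medians were -1.11 over all cells, 0.0411 in B (reversed), -0.31 in NK, -1.38 in alpha-beta T, -0.31 in gamma-delta T cells and -0.79 in monocytes. In male cells only, also chosen after, the shares were -3.54 for B (reversed), -1.35 for NK (within the counting error), 9.03 for alpha-beta T, 2.57 for cluster 7 (reversed), -5.68 for monocytes, 10.1 for cluster 21 and 4.25 for cluster 22. The interferon medians were -1.98 over all cells, -1.28 in B, -1.05 in NK, -2.59 in alpha-beta T, 0.29 in cluster 7 (reversed), -1.71 in type 2 dendritic cells and -1.54 in monocytes. The alpha-beta T share difference was 2.79 at Leiden 0.5, 4.35 at a UMI minimum of 500, 4.01 at a mitochondrial maximum of 5% and 2.73 with clusters 18 and 22 counted in. That of monocytes was -5.65 with cluster 7 counted in, that of cluster 21 was 4.90 at Leiden 2.0, and that of cluster 22 was 4.13 at a UMI minimum of 2000. With each library clustered on its own, the shares of gamma-delta T cells (0.543) and monocytes (3.63) reversed, because the knockout monocyte class took 304 of 304 cells of cluster 7 against 6 of 316 in flox, and the knockout gamma-delta T class 54 of 54 cells of cluster 6 against 0 of 40. That of cluster 7 (0.295) reversed too, where the matching cluster had a Jaccard of 0.963 in flox and 0.806 in knockout. There the interferon median was -1.61 in type 2 dendritic cells and -1.35 in monocytes, and proliferation in type 2 dendritic cells (0.60), T cell activation (-0.29) and Il17a (-0.31) in gamma-delta T cells reversed. With cells thinned to 1000 UMIs, the interferon median was -0.22 in B, -0.82 in NK, -1.27 in cluster 18, -0.41 in cluster 7 and -0.35 in type 2 dendritic cells. Reversed there were Il17ra over all cells (0.00300), Pycard in B (0.17), immediate early (-0.0668) and glycolysis genes (0.0489) in NK, Frmd4b in cluster 18 (-0.25), IL-17 receptor signalling in cluster 7 (-0.0538), oxidative stress in type 2 dendritic cells (-0.0118), T cell activation in gamma-delta T cells (-0.0210) and MHC class II in monocytes (0.0714). Without cluster 13, Lgals1 (0.34), Ddt (0.0880), Ahnak (0.19) and Pycard (0.38) reversed in B, and without cluster 21, the cytotoxic list (-0.36), Zeb2 (-0.0418) and Ccl4 (-0.40) in alpha-beta T cells. Cluster 13 held 79.8% to 92.2% of the flox UMIs of these B cell genes, and cluster 21 held 76.0% and 69.7% of the knockout UMIs of Zeb2 and Ccl4, but neither held most of them in the other library. Without the knockout cell with most Ccl5 UMIs, also chosen after, the cytotoxic list in gamma-delta T cells reversed (-0.23). Without a UMI minimum, inflammatory genes in NK (-0.17) and T cell activation in gamma-delta T cells (-0.0216) reversed. With doublets kept, MHC class II in alpha-beta T cells reversed (0.00825), and the difference in share of cells with a UMI, Il17a, gamma-delta T, was -11.1 points. With the mean of each cell's CPM, MHC class II in monocytes reversed (0.0653), and the interferon median was -0.74 in type 2 dendritic cells and -0.81 in monocytes. Without the highest cell per gene, the list median, type I interferon response, cluster 18, was -2.30, and in type 2 dendritic cells it was -1.20. No value was obtained for clusters 18 and 22 at Leiden 0.5 (best Jaccard 0.426 and 0.210), nor with each library on its own for clusters 21 (0.0525) and 22 (0.0298) in flox and 18 in knockout (0.391), nor for the interferon list in male cells of cluster 18 and gamma-delta T cells. With cells thinned to 1000 UMIs, too few members were left for the interferon list of gamma-delta T cells and for many other lists.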

Other observations

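The tests of cluster 15 and of cells without sex transcripts were chosen only after the result was seen, and that of cluster 13 when the single frequencies were known.

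The interferon difference and the T cell differences touch genes of 1 axis. Cxcl10, which draws T cells that bear Cxcr3, was 11.1-fold lower in knockout monocytes, while Ifng, which can induce it, was higher over all cells (47.6 and 99.4 CPM). The type I interferon list was also lower in monocytes (median -0.99) and in cluster 7 (median -0.69). Lower Cxcl10 and Iigp1 in monocytes and cluster 7 could be part of that same decrease. The values do not tell responses to the interferon types apart. Beside more Ifng, they could also mean that these cells respond less to interferon-gamma, or that the Ifng was made elsewhere or during digestion. The MHC class II median was -1.42 in cluster 7, -0.21 in alpha-beta T cells, -0.17 in NK cells, -0.10 in type 2 dendritic cells and -0.08 in monocytes, where it was 0.0714 with cells thinned to 1000 UMIs; differences between classes were not tested. These lists were not split by sex, so an effect of the sex mix stays untested. Interferon-gamma given to monocytes of both genotypes in culture, with Cxcl10 measured, would test the response to interferon-gamma.

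Some cells of clusters 15 and 13 of the flox library share receptor segments as clones do. T cell receptor and immunoglobulin genes were not left out of this clustering, so shared segments may have helped to form these clusters. Cluster 15 was not followed in the clustering without T cell receptor genes. In cluster 15, of 37 flox cells, 2.70% had a Trbc1 UMI against 60.5% of other flox alpha-beta T cells, and 32.4% had Trav12-2 against 0.370%, in line with 1 clone that uses the other constant gene, Trbc2. Both Trbv12-2 and Trbv13-2 were found in 16.2%, above the 5.65% and 3.24% of other flox alpha-beta T cells. Of 6 cells with the former 3 also had the latter, against 3 of 31 others, too few cells to exclude more than 1 clone. In cluster 13 of the flox library, 31.5% of cells had Igkv8-30, and of the cells with Ighv6-6, 91.7% also had Igkv8-30 against 14.3% of the others, in line with 1 B cell clone among them. The cluster also held 27 knockout cells, 0 of them with Igkv8-30. The 17 Igkv8-30 cells held between 38.1% (Syne1) and 77.9% (Ddt) of the flox B cell UMIs of the genes named as lower, so much of these differences lies in few cells. Without cluster 13 the ratio was still 0.564 (0.410 to 0.778) for Ccnd2, 0.708 (0.520 to 0.966) for Syne1 and 0.788 (0.626 to 0.993) for Itgb1, and nothing here separates such a clone from the genotype.

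In cluster 22, 27.3% of knockout cells had Trav21-dv12. Of these, 96.6% had neither Xist nor Y-linked UMIs, against 38.9% of the other knockout cells of the cluster. Low depth is excluded as the cause, with a median of 8005 UMIs against 7231. A clone that has lost the Y chromosome, or Xist expression, is possible and was not tested; DNA of sorted cells would show it.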
